A study of Mus musculus with 6 samples.

How the data were processed

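Gene expression was measured on Affymetrix mouse M430 2.0 arrays in immortalized mouse embryonic fibroblasts that lack Kdm5a, the gene of a demethylase acting on lysine 4 of histone H3. The cells carried an empty vector, wild-type KDM5A, or KDM5A-H483A, in which a histidine of the catalytic domain is replaced by alanine. Per the labels' protocols, total RNA came from subconfluent cultures grown in serum-containing medium and harvested with trypsin, with DNA digested on the column during extraction. The same protocols name a labelling kit for whole transcripts, while the probe sets of this array type lie towards the 3' ends, and the sources used here do not say how the 2 were combined. There were 2 arrays per group and 6 in all. The labels call the 2 arrays of a group biological replicates without saying how the cultures were separated, so p-values measure the spread between these samples.

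The authors deposited 1 table of log2 expression values, made with RMA per the submitters' processing notes. RMA subtracts background, quantile-normalizes the arrays and summarises the probes of each probe set on the log2 scale. The RMA software version and the probe annotation used are not given in the sources used here. Values of all 6 arrays had medians between 4.55 and 4.60 and lay between 2.12 and 14.1, so the deposited log2 values were used without further scaling. Quantile normalization assumes that the arrays share 1 distribution, so a change in total RNA per cell cannot be seen, and RMA compresses differences of weakly expressed genes. An array value carries no count of molecules. The number of arrays limits the precision.

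The table held 45101 probe sets. The platform annotation paired 34958 of them with 1 gene symbol and 932 with several, and listed none for 9211, of which 64 were controls of the array maker. Symbols were updated through Entrez IDs to those of the mouse reference gene table, which matched 34754 of the single-gene probe sets. Each gene was represented by its probe set with the highest mean over the 6 arrays among those whose ID does not end in _x_at, the suffix of probe sets that can cross-hybridize. Another kind was taken for the 100 genes with no other probe set. This left 18194 genes, 9012 of them with more than 1 probe set. Genes that this table does not hold were not analysed here.

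Differences were tested with limma (version 3.58.1, in R 4.3.3): lmFit with 1 mean per group over all 6 arrays, then eBayes, with 3 residual degrees of freedom and a prior of 3.42 degrees of freedom estimated from all genes. The 3 comparisons were wild-type KDM5A against empty vector, KDM5A-H483A against empty vector, and KDM5A-H483A against wild-type KDM5A. P-values were two-sided and adjusted over all 18194 genes by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are given on the log2 scale with their moderated standard error and 95% confidence interval. Group means are given with the SD over n = 2 arrays.

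The groups, tests, gene lists and the rule for named genes were fixed before the data were examined. The 47 gene lists came from textbook knowledge and held 1086 genes, of which 998 (91.9%) were measured. The 43 lists with at least 5 measured members were tested with limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 43 lists. Camera asks whether a list's genes stand apart from all other genes. It was repeated with a correlation estimated for each list. Camera then takes its p from the 3 residual degrees of freedom, which leaves little power over 43 lists. Limma's fry was run as a test of whether a list's own genes move 1 way. The members of each list were also adjusted over the list alone. For each comparison, the rule named the genes past the threshold with the largest changes. Where fewer than 5 passed in a direction, it named the 5 with the smallest unadjusted p in that direction, described as not past the threshold. It also named the KDM5 family and up to 2 members with the largest absolute change from each list that was called. Genes known only by a clone, RIKEN or predicted-gene symbol were passed over in naming and kept in the totals. A gene named in both comparisons against empty vector or in another pair of comparisons, and the first gene of each, are also given in the remaining comparison, a choice made after the values were seen.

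The procedure was tested on simulated data before use. With no effect in simulated arrays, limma called 0 genes in each comparison, and camera with the preset correlation called 0, 0 and 1 lists in the order of comparisons above. The simulated errors were independent between genes, while the correlation estimated within the lists reached 0.82, so these counts do not cover correlated genes. With 200 genes shifted in the real arrays by 0.5 or by 1 on the log2 scale, limma recovered 0% of them in each comparison. For a shift of 2 it recovered 91.5% for wild-type KDM5A against empty vector, 94% for KDM5A-H483A against empty vector and 92.5% for KDM5A-H483A against wild-type KDM5A. These shares apply to 200 genes shifted together, and fewer shifted genes would need larger shifts to pass.

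The 2 comparisons against empty vector share the same empty vector arrays. The covariance of their fold changes was set beside 100 simulations in which no group differed, with the spread pooled over groups and with each group's own spread. Errors in these simulations were independent between genes. The simulation with each group's own spread was added after the data were seen. Alternatives were the replicate number as a block, only the 4 arrays compared, a trended robust prior, another quantile normalization, centring on the array median, only genes at or above the median level, the mean of all probe sets of a gene, all probe sets tested singly, stricter thresholds, and leaving out each array in turn. Array weights per group and leaving out the second arrays of both KDM5A groups were chosen after seeing the data.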

Results

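Expression profiles of Kdm5a-null mouse embryonic fibroblasts were compared after reintroduction of wild-type KDM5A or of KDM5A-H483A, with an empty vector as control. The design asks which genes respond to KDM5A in these cells, and which of these responses differ when the catalytic histidine is replaced. Each of the 3 groups was measured on 2 arrays, as log2 RMA values for 18194 genes. Pearson's r across genes, which are not independent replicates, was 0.994 between the empty vector arrays, 0.986 between the wild-type KDM5A arrays and 0.983 between the KDM5A-H483A arrays. The first KDM5A-H483A array reached 0.995 both with the first empty vector array and with the first wild-type KDM5A array, above each of these 3 values. No pair of arrays shared more than 110 identical gene values, so none was a repeat of another.

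Within each KDM5A group, the 2 arrays differed in genes of the extracellular matrix, the interferon response and ribosome biogenesis, among others. Col3a1, which encodes a fibrillar collagen, stood at 13.1 and 10.5 in the first and second wild-type KDM5A arrays and at 12.9 and 10.2 in the KDM5A-H483A arrays, against 12.7 and 12.3 with empty vector. Postn, the gene of the matrix protein periostin, stood at 9.65 and 6.08, at 9.29 and 6.29, and at 9.16 and 8.42 in the same order. Ifit1, an interferon-induced antiviral gene, stood at 9.41 and 5.73, at 8.87 and 5.26, and at 7.23 and 6.59. The second arrays were instead higher for Ankrd1, a nuclear ankyrin-repeat factor, at 6.02 against 4.28 for wild-type KDM5A and 7.08 against 4.88 for KDM5A-H483A, and for Utp18, a ribosome assembly factor, at 7.52 against 6.22 and 7.85 against 6.59. These genes were chosen after their values were seen. The median gene of the matrix list was higher in the first array than in the second by 0.78 for wild-type KDM5A and 0.83 for KDM5A-H483A, and by 0.16 for empty vector. For the list of ribosome biogenesis and Myc targets this difference was -0.46, -0.78 and 0.02. Replicate arrays lay at least 1 log2 unit apart for 27 genes with empty vector, 337 genes with wild-type KDM5A and 436 genes with KDM5A-H483A. Differences between group means held 31.5% of the variance over all genes, where 40% would be expected with no group effect, and the first principal component, with 49.1% of the variance, ordered the first KDM5A arrays at -23.0 and -15.0 and the second at 13.7 and 34.1.

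**Figure D1:**
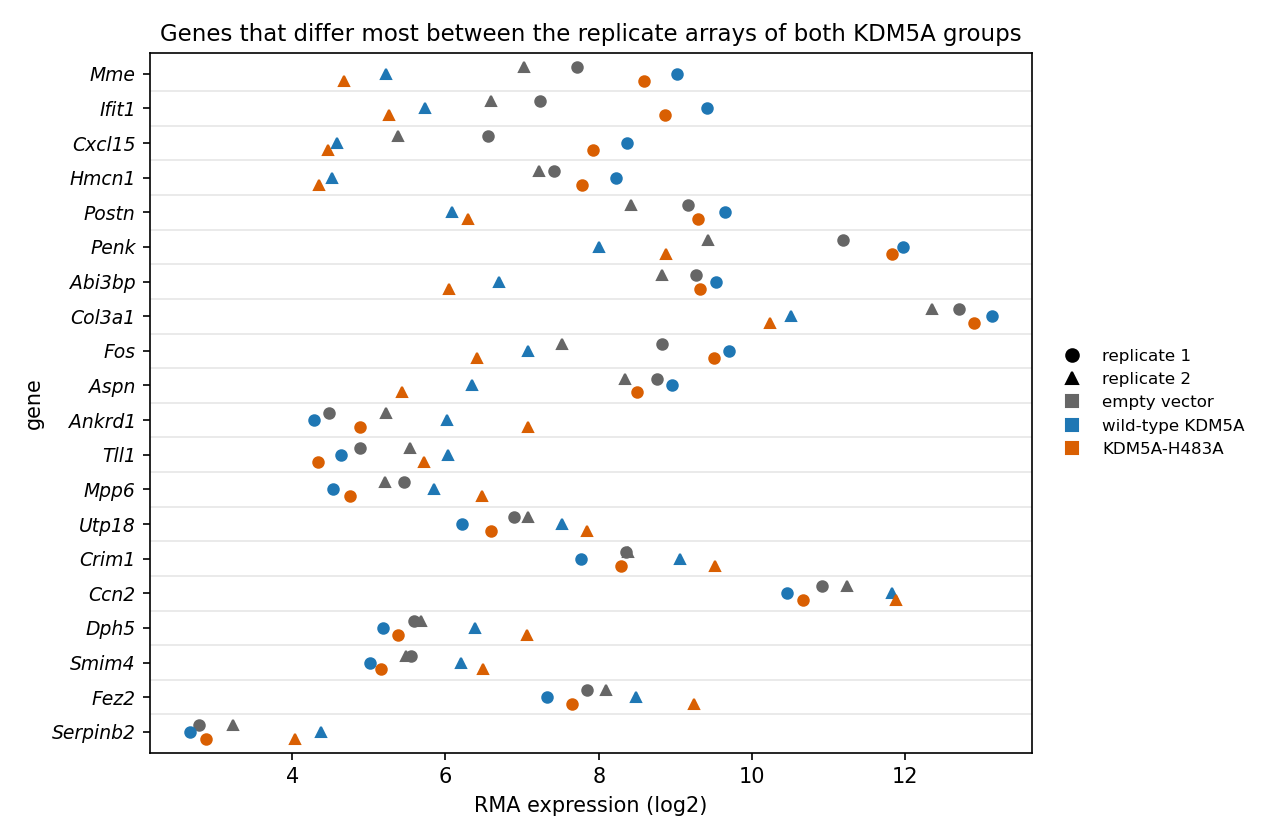
Log2 RMA expression (horizontal axis) of the 10 genes most higher and the 10 most lower in the first array than in the second in both KDM5A groups (vertical axis), with circles for replicate 1, triangles for replicate 2 and colours for the groups. The empty vector arrays lie closer together than the arrays of either KDM5A group for Col3a1, where the second KDM5A arrays stand at 10.5 and 10.2 and the other 4 arrays between 12.3 and 13.1.

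Kdm5a itself did not pass the threshold in any comparison. Its brightest probe set (1452360_a_at) stood at 5.89 and 5.83 with empty vector, 5.96 and 5.83 with wild-type KDM5A, and 6.11 and 5.89 with KDM5A-H483A. The log2 fold change against empty vector was 0.03 (SE 0.13, 95% CI -0.29 to 0.36, limma adjusted p = 1) for wild-type KDM5A and 0.14 (SE 0.13, 95% CI -0.18 to 0.46, limma adjusted p = 0.999) for KDM5A-H483A. A second probe set (1437105_at) stood at 5.63 and 5.85, 6.14 and 5.5, and 5.48 and 4.85 in the same order. Both KDM5A-H483A arrays stood below both empty vector arrays in this second probe set. In the first probe set the lower KDM5A-H483A array and the higher empty vector array were level at 5.89. The other 4 probe sets lay between 3.01 and 4.62 in every array. Where these probes lie relative to the deleted part of the gene and to the reintroduced sequence is not given in the sources used here, so the values check neither the deletion nor the reintroduction. Of its relatives, Kdm5b stood at 7.53 ± 0.34, 7.46 ± 0.14 and 7.74 ± 0.07 (SD, n = 2) with empty vector, wild-type KDM5A and KDM5A-H483A, and Kdm5c at 7.67 ± 0.19, 7.85 ± 0.17 and 7.62 ± 0.16. The Y-linked Kdm5d stood at 6.52 ± 0.07, 6.39 ± 0.33 and 6.03 ± 0.47. None of the 4 genes passed the threshold in any comparison, with limma adjusted p of at least 0.928.

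Fibroblasts with wild-type KDM5A had the smallest p against empty vector for Npnt, the gene of the matrix protein nephronectin, which was 2.27-fold higher. Npnt stood at 6.66 ± 0.06 against 5.47 ± 0.01 (SD, n = 2), a log2 fold change of 1.19 (SE 0.13, 95% CI 0.87 to 1.5, unadjusted p = 6.36e-05, limma adjusted p = 1). The chemokine gene Ppbp was 1.65-fold higher and the water channel gene Aqp1 1.75-fold higher, with log2 fold changes of 0.72 (95% CI 0.38 to 1.06) and 0.81 (95% CI 0.41 to 1.20). Mycn, a MYC family transcription factor, was 1.78-fold lower (log2 fold change -0.84, 95% CI -1.23 to -0.44), and the growth factor gene Fgf9 was 1.83-fold lower (log2 fold change -0.87, 95% CI -1.31 to -0.43). None of these differences passed the threshold.

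The other genes that the rule named in this comparison were Pon3, a lactonase gene (log2 fold change 0.67), and Stam, an endosomal sorting adaptor (0.57), on the higher side. On the lower side they were Chodl, a membrane lectin gene (-0.80), Rdh11, a retinal reductase gene (-0.64), and Btla, a lymphocyte inhibitory receptor gene (-0.53). The Btla signal was weak, with a mean level at the 36.2nd percentile of all probe sets, and may not lie above background. All 10 genes had both arrays of 1 group above both of the other. Over all genes, 31.8% were separated in this way, where chance gives 33.3%. A second Npnt probe set (1452106_at) was higher as well, at 6.77 and 6.84 against 5.02 and 5.26, and the remaining 3 Npnt probe sets had log2 fold changes of 0.37, 0.08 and 0.01. The Mycn values come from a probe set (1425923_at) near 12, while the other 2 Mycn probe sets stayed between 3.44 and 4.10 in all arrays, with log2 fold changes of -0.06 and -0.05. The other probe sets had log2 fold changes of 0.06 for Fgf9, -0.12 for Rdh11, and 0.34, -0.40 and 0.24 for Stam.

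Limma called 0 of 18194 genes between wild-type KDM5A and empty vector, with a smallest adjusted p of 1. At an unadjusted p under 0.05 there were 459 genes, 275 higher and 184 lower, where 909.7 would be expected by chance. The fit has no replicate block, so differences between replicate numbers that groups share count as error and can raise p. A count below chance therefore does not show that genes were unchanged. The median gene had a 95% confidence interval of 0.37 to either side of its log2 fold change. Shifts of 1 log2 unit in 200 genes were not recovered in the self-test. Differences of that size in that many genes would therefore not have passed the threshold in this comparison.

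Of the gene lists, 5 stood above the other genes in wild-type KDM5A cells by camera with the preset correlation. None of these 5 calls held with an estimated correlation (adjusted p = 0.999 for each), and fry called 0 lists. A larger correlation was not the only reason for the loss, because this form of camera also rests on the 3 residual degrees of freedom. With so few, hardly any list could pass, so the loss alone does not show that a list was unchanged. For immediate early genes the estimate was -0.02, below the preset 0.01, yet camera's unadjusted p rose from 0.00248 to 0.0426. Lysosome and autophagy genes had a median log2 fold change of 0.21, with 27 of 29 members above 0 (camera adjusted p = 0.000742). Members with the largest differences were Gla, a lysosomal galactosidase (0.48, 95% CI -0.18 to 1.14), and Gabarap, an autophagosome protein (0.46, 95% CI -0.06 to 0.98). Genes activated by p53 had a median of 0.30, with 16 of 22 above 0 (camera adjusted p = 0.00302), among them the apoptosis gene Pmaip1 (0.70, 95% CI -0.46 to 1.85) and the receptor gene Eda2r (0.59, 95% CI 0.03 to 1.14). Interferon-stimulated genes had a median of 0.27, with 34 of 44 above 0 (camera adjusted p = 0.0176). Usp18, which removes the ubiquitin-like modifier ISG15, stood at 6.78 and 4.31 against 4.51 and 4.38, and Xaf1, an apoptosis factor, at 7.62 and 4.83 against 5.70 and 4.95. Glycolysis and hypoxia genes had a median of 0.13, with 21 of 31 above 0 (camera adjusted p = 0.0196), among them the hypoxia-induced Adm (0.47, 95% CI -0.22 to 1.16) and Bnip3 (0.40, 95% CI -0.04 to 0.84). Immediate early genes had a median of 0.15, with 21 of 27 above 0 (camera adjusted p = 0.0213), among them the transcription factors Klf4 (0.63, 95% CI 0.11 to 1.15) and Nr4a2 (0.60, 95% CI -0.40 to 1.60). Of the members of these lists, 0 passed over all genes or adjusted over the list alone. Without the second empty vector array, camera called 0 lists (adjusted p between 0.104 and 0.397), although the medians were 0.19 for lysosome, 0.21 for p53 target, 0.25 for interferon-stimulated, 0.13 for glycolysis and 0.18 for immediate early genes. Camera called 9 lists without the first wild-type KDM5A array and 14 without the second. Without the first, the interferon median was -0.14 (adjusted p = 0.0614), the lysosome median 0.01 (0.423) and the p53 target median 0.05 (0.226). The glycolysis call also ended without the first (adjusted p = 0.353) and the immediate early call without the second (0.111), both at medians of 0.16, no smaller than with all arrays. The medians without the second were 0.63 for interferon-stimulated genes, 0.34 for the lysosome and 0.24 for glycolysis, and the immediate early median was 0.27 without the first empty vector array.

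Fibroblasts with KDM5A-H483A likewise had the smallest p against empty vector for Npnt, which was 1.92-fold higher, at 6.41 ± 0.15 against 5.47 ± 0.01 (SD, n = 2), a log2 fold change of 0.94 (SE 0.13, 95% CI 0.63 to 1.25, unadjusted p = 0.000253, limma adjusted p = 0.999). Retsat, a retinol saturase gene, was 1.77-fold higher (log2 fold change 0.83, 95% CI 0.49 to 1.16), and Mlkl, the effector of necroptosis, was 1.61-fold higher (log2 fold change 0.69, 95% CI 0.39 to 0.98). Moxd1, a monooxygenase gene, was 2.11-fold lower (log2 fold change -1.08, 95% CI -1.55 to -0.60), and Rgs5, a regulator of G protein signalling, was 1.80-fold lower (log2 fold change -0.85, 95% CI -1.25 to -0.45). None of these differences passed the threshold.

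The rule also named Manba, a lysosomal mannosidase gene (log2 fold change 0.72), and Ppbp (0.72) on the higher side, and Chodl (-0.84), Mycn (-0.82) and Slc17a6, a vesicular glutamate transporter gene (-0.76), on the lower side. The second Npnt probe set stood at 6.24 and 6.44 with KDM5A-H483A, against 5.02 and 5.26. The remaining 3 Npnt probe sets had log2 fold changes of 0.07, 0.79 and 0.03. The other probe sets had log2 fold changes of 0.06 for Retsat, -0.13 for Slc17a6, -0.02 and 0.10 for Mycn, and -0.43, 0.08 and -0.04 for Rgs5. Limma called 0 of 18194 genes, with a smallest adjusted p of 0.999. At an unadjusted p under 0.05 there were 301 genes, 176 higher and 125 lower, where 909.7 would be expected by chance, and 28.2% of genes had arrays apart, where chance gives 33.3%. Here too a count below chance does not show that genes were unchanged.

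**Figure D2:**
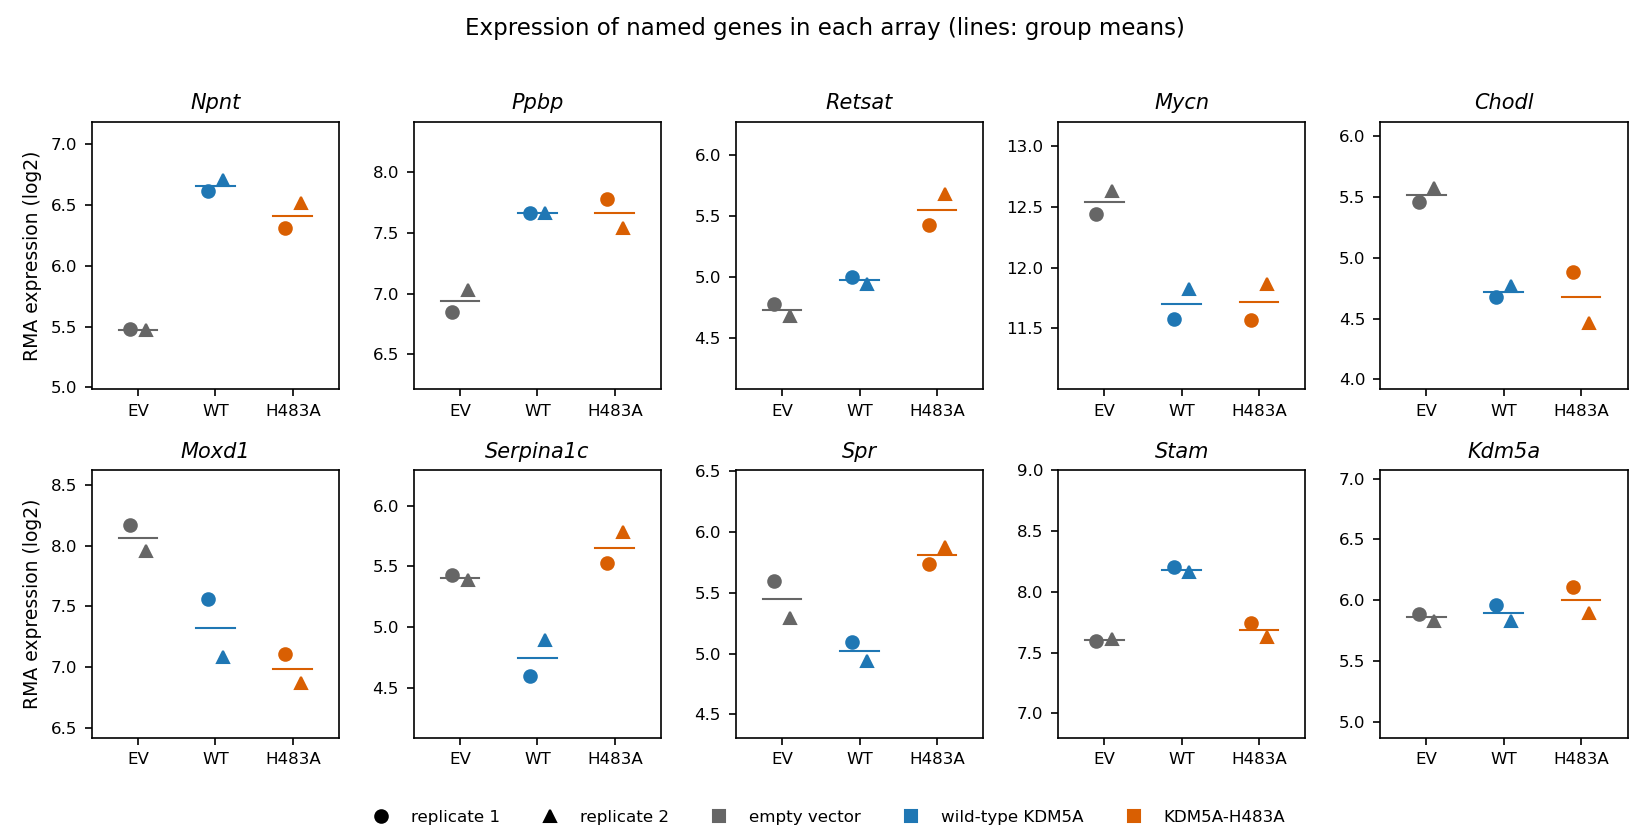
Log2 RMA expression (vertical axes, each spanning 2.2 log2 units) of 10 named genes in each array of the empty vector (EV), wild-type KDM5A (WT) and KDM5A-H483A (H483A) groups, with circles for replicate 1, triangles for replicate 2 and lines for group means. Npnt lies at 5.47 with empty vector and at 6.66 and 6.41 with the KDM5A forms, Mycn at 12.5 and at 11.7 in both, and Kdm5a between 5.83 and 6.11 in all 6 arrays.

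Camera with the preset correlation set 8 gene lists apart between KDM5A-H483A and empty vector, 7 higher and 1 lower. None of the 8 calls held with an estimated correlation (adjusted p = 0.940 for each), and fry called 0 lists. Here too a larger correlation was not the only reason, and with 3 residual degrees of freedom the loss alone does not show unchanged lists. For immediate early genes, with an estimate of -0.02, camera's unadjusted p rose from 0.000137 to 0.0234. Lysosome and autophagy genes had a median log2 fold change of 0.17, with 23 of 29 members above 0 (camera adjusted p = 0.000274), among them the hexosaminidase gene Hexa (0.76, 95% CI -0.15 to 1.68) and the cathepsin gene Ctsl (0.63, 95% CI -0.18 to 1.43). Glycolysis and hypoxia genes had a median of 0.17, with 25 of 31 above 0 (camera adjusted p = 0.00111), among them the phosphofructokinase genes Pfkl (0.50, 95% CI -0.04 to 1.05) and Pfkp (0.46, 95% CI -0.21 to 1.13). Immediate early genes had a median of 0.17, with 22 of 27 above 0 (camera adjusted p = 0.00196), among them the matricellular gene Ccn1 (0.62, 95% CI -0.12 to 1.35) and Ier5 (0.57, 95% CI -0.27 to 1.42). Genes activated by p53 had a median of 0.14, with 15 of 22 above 0 (camera adjusted p = 0.00345), among them Pmaip1 (0.96, 95% CI -0.20 to 2.11) and the desmosome-associated Perp (0.92, 95% CI 0.19 to 1.64). Without the first and the second KDM5A-H483A array the glycolysis median was 0.27 and 0.08, and the p53 target median 0.12 and 0.34. Of the members of the 8 lists, 0 passed over all genes or adjusted over the list alone.

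The other 4 calls in this comparison were lost with an estimated correlation as well (adjusted p = 0.940 for each). Mitochondrial ribosome genes had a median of 0.23, with 29 of 36 above 0 (camera adjusted p = 0.0038), and Mrpl12 stood at 5.69 and 7.12 against 6.0 and 5.89, Mrps25 at 5.74 and 7.11 against 6.13 and 5.49. Genes of ribosome biogenesis and Myc targets, called ribosome biogenesis below, had a median of 0.23, with 27 of 31 above 0 (camera adjusted p = 0.0244), and the nucleolin gene Ncl stood at 9.63 and 11.4 against 10.1 and 9.62, Rrp12 at 4.84 and 6.03 against 4.93 and 4.93. Heat shock proteins had a median of 0.20, with 12 of 14 above 0 (camera adjusted p = 0.0345), and the chaperone gene Hspa8 stood at 9.92 and 10.9 against 10.3 and 9.67, its co-chaperone Bag3 at 7.18 and 7.82 against 7.03 and 6.77. Collagen and extracellular matrix genes had a median of -0.21, with 36 of 48 below 0 (camera adjusted p = 0.0345), and Aspn, a small leucine-rich proteoglycan, stood at 8.5 and 5.43 against 8.76 and 8.34, the fibrillin gene Fbn2 at 8.97 and 6.25 against 9.11 and 9.0. Without the second KDM5A-H483A array camera called the mitochondrial ribosome (median -0.14, adjusted p = 0.00686) and ribosome biogenesis (-0.23, adjusted p = 6.25e-05) in the opposite direction, and heat shock proteins (0.01, adjusted p = 0.563) and the matrix (0.18, adjusted p = 0.0608) in neither. Without the first array of that group the medians of these 4 lists were 0.57, 0.62, 0.31 and -0.62. Camera called 14 lists without the first or without the second KDM5A-H483A array, and 5 without the second empty vector array. Leaving out the first empty vector array ended the matrix (median -0.14, adjusted p = 0.420), heat shock (0.13, adjusted p = 0.197) and ribosome biogenesis (0.19, adjusted p = 0.253) calls. Leaving out the second ended the p53 target (0.09, adjusted p = 0.105), heat shock (0.20, adjusted p = 0.0502) and mitochondrial ribosome (0.14, adjusted p = 0.0830) calls, and leaving out the first KDM5A-H483A array ended the p53 target call (0.12, adjusted p = 0.124).

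**Figure D3:**
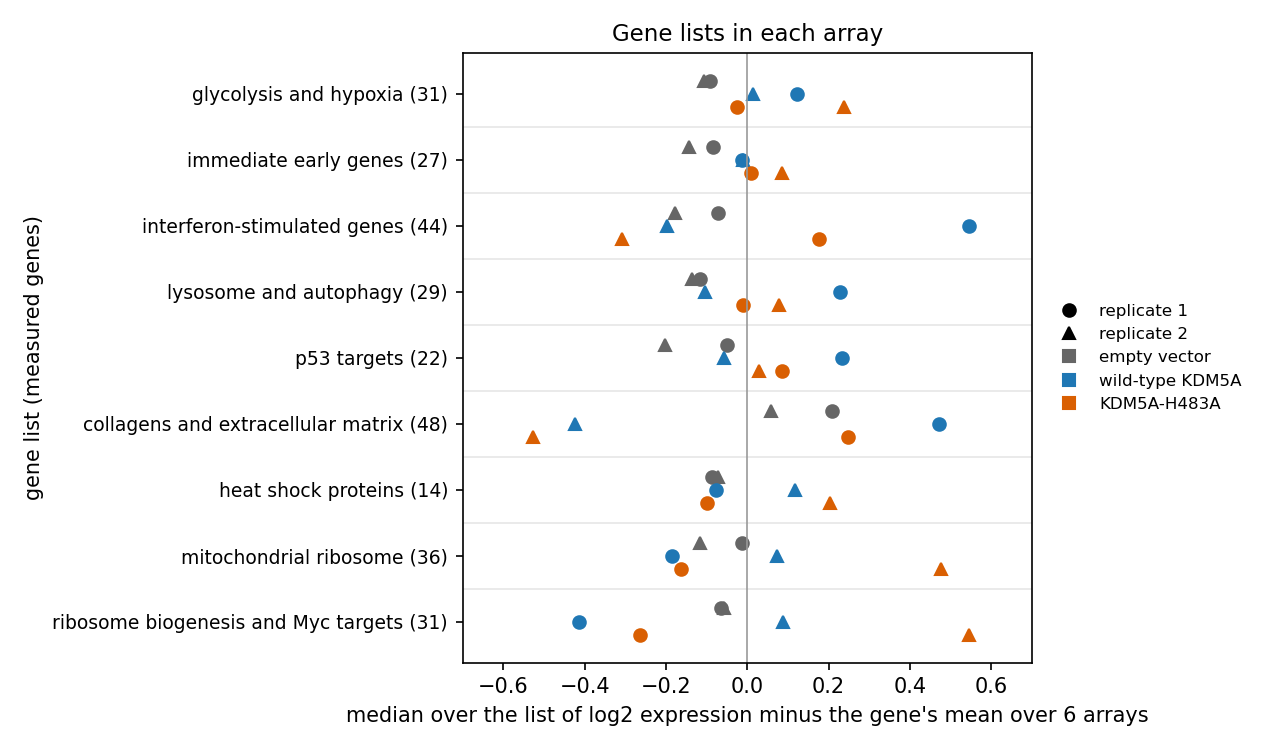
Median over each gene list of log2 expression relative to the gene's mean over the 6 arrays (horizontal axis), for the 9 lists called in any comparison (vertical axis, with the number of measured genes), with circles for replicate 1, triangles for replicate 2 and colours for the groups. For ribosome biogenesis and Myc targets the second KDM5A-H483A array lies at 0.55 and the first at -0.26, on either side of the empty vector arrays at -0.06 and -0.06.

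Npnt, Ppbp, Mycn and Chodl were named in both comparisons against empty vector, which share the same control arrays. Across genes, which are not independent replicates, the 2 sets of log2 fold changes had a Pearson r of 0.34 and a Spearman rho of 0.29, and a covariance of 0.0115. Simulated groups with no effect and each group's own spread gave a mean r of 0.27 (range 0.21 to 0.32), a mean rho of 0.34 (0.32 to 0.35) and a mean covariance of 0.0128 (0.0104 to 0.0147), and with the spread pooled over groups 0.50, 0.46 and 0.0277. The observed covariance differed from these simulated means by -0.00129 and -0.0161. At an unadjusted p under 0.05, 44 genes were higher in both and 30 lower in both, where the simulations gave means of 168 and 168 with each group's own spread and independent lists would share 2.66 and 1.26. Shared controls alone gave more shared genes in the simulations than were observed. The excess over independent lists therefore cannot be read as a response common to both KDM5A forms. The observed lists held 459 and 301 genes, where 909.7 would be expected by chance, so the simulated counts are not matched to them in size. The 2 empty vector arrays cannot be split into sets of 2, and giving 1 of them to each KDM5A form was not tried.

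The direct comparison of KDM5A-H483A with wild-type KDM5A, which tests whether the H483A form acts differently, was led by Serpina1c, a member of the mouse alpha-1 antitrypsin gene family. It was 1.88-fold higher with KDM5A-H483A, at 5.65 ± 0.18 against 4.75 ± 0.21 (SD, n = 2), a log2 fold change of 0.91 (SE 0.16, 95% CI 0.53 to 1.29, unadjusted p = 0.000924, limma adjusted p = 0.928). With empty vector Serpina1c stood at 5.41 ± 0.03, and the log2 fold change against it was -0.66 for wild-type KDM5A and 0.25 for KDM5A-H483A. Spr, a sepiapterin reductase gene of tetrahydrobiopterin synthesis, was 1.73-fold higher (log2 fold change 0.79, 95% CI 0.42 to 1.16). Dcun1d1, a neddylation cofactor, was 1.56-fold lower (log2 fold change -0.64, 95% CI -1.02 to -0.27), and Itch, a ubiquitin ligase gene, was 1.5-fold lower (log2 fold change -0.59, 95% CI -0.89 to -0.28). None of these differences passed the threshold.

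The rule also named Commd5 (log2 fold change 0.62), the semaphorin gene Sema6c (0.60) and the ciliary gene Evc (0.52) on the higher side. On the lower side it named Zfp763, a zinc finger gene (-0.64), Chac2, a glutathione-degrading enzyme (-0.55), and Stam (-0.50), which stood at 8.18 ± 0.03 with wild-type KDM5A against 7.68 ± 0.08 with KDM5A-H483A and 7.61 ± 0.01 with empty vector. The other probe sets had log2 fold changes of -0.31, 0.45 and 0.03 for Stam, 0.11, -0.12, -0.10 and -0.24 for Dcun1d1, 0.12, 0.07 and -0.08 for Itch, -0.29 and 0.33 for Commd5, 0.24 and 0.02 for Sema6c, 0.19 for Evc and -0.12 for Zfp763. Of the genes shared by the comparisons against empty vector, Npnt had a log2 fold change of -0.25 between the KDM5A forms (95% CI -0.56 to 0.06), Mycn 0.01 (95% CI -0.38 to 0.41), Ppbp 0.00021 (95% CI -0.34 to 0.34) and Chodl -0.05 (95% CI -0.45 to 0.35). The other Npnt probe sets disagreed in sign, at -0.46, -0.30, 0.71 and 0.02, and the other Mycn probe sets stood at 0.03 and 0.15. Limma called 0 of 18194 genes, with a smallest adjusted p of 0.928. At an unadjusted p under 0.05 there were 694 genes, 340 higher and 354 lower, where 909.7 would be expected by chance, and 31% of genes had arrays apart, where chance gives 33.3%. The replicate deviations of the KDM5A groups correlated across genes with r = 0.53. With no block in the fit, this shared part counts as error and can raise p, so the low count does not show unchanged genes.

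Ribosome biogenesis was the 1 list that camera with the preset correlation set apart between the KDM5A forms. Its median log2 fold change was 0.24, with 26 of 31 members higher with KDM5A-H483A (camera adjusted p = 0.00836), and adjusted p = 0.998 with an estimated correlation. Fry called 0 lists, and 0 members passed over all genes or adjusted over the list alone. Ncl had a log2 fold change of 0.98 (95% CI -0.31 to 2.28), and Nolc1, a nucleolar phosphoprotein gene, stood at 6.62 and 7.88 against 5.94 and 6.95. Without the second KDM5A-H483A array the median was -0.14, and without the first wild-type KDM5A array it was 0.06, with camera pointing down (adjusted p = 0.871). It was 0.68 without the first KDM5A-H483A array and 0.53 without the second wild-type KDM5A array. Camera called 3 and 13 lists without the first and second wild-type KDM5A arrays, and 10 and 7 without those of KDM5A-H483A, and it called 1 list for this comparison in simulated arrays with no effect and independent errors.

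Several lists fixed for their link to KDM5A were not called. The 6 genes reported to be bound by KDM5A had camera adjusted p of 0.995, 0.527 and 0.718 in the 3 comparisons, taken in the order above. The 17 other histone lysine demethylases had 0.644, 0.516 and 0.253, and the 12 genes of the complexes that methylate lysine 4 of histone H3 had 0.348, 0.682 and 0.231. Genes of DNA replication and the G1/S transition had 0.995, 0.109 and 0.231, those of oxidative phosphorylation 0.995, 0.119 and 0.323, and Hox genes 0.778, 0.527 and 0.885. Markers of epithelial, endothelial, leukocyte, neural and muscle cells had adjusted p of at least 0.231 in every comparison.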

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

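Array weights per group, leaving out the second arrays of both KDM5A groups, and the simulation with each group's own spread were chosen after seeing the data. The number of genes called stayed at 0 in all 54 combinations of comparison and alternative run with limma. Over them the smallest adjusted p was 0.0801 for wild-type KDM5A against empty vector, 0.270 for KDM5A-H483A against empty vector and 0.230 between the KDM5A forms, and the genes at an unadjusted p under 0.05 ranged from 138 to 1675, from 71 to 2079 and from 245 to 2335. Of these alternatives, the stricter thresholds could only give 0 genes, because the main fit had called 0. Fits on fewer arrays kept fewer residual degrees of freedom than the main fit, so their result adds little. The labels do not say whether the replicate numbers pair the samples. The replicate deviations correlated across genes with r = 0.53 between the KDM5A groups, 0.31 between empty vector and wild-type KDM5A and 0.02 between empty vector and KDM5A-H483A. Of the 6 arrays, 5 correlated best with an array of their own number. The KDM5A groups thus shared a difference between replicate numbers, which the main fit, having no block, ignores. With the replicate block limma still called 0 genes, and camera called 7, 10 and 3 lists in the 3 comparisons, against 5, 8 and 1 without it. In the same order of comparisons, camera called 3, 6 and 2 lists after another quantile normalization, 1, 8 and 2 among genes at or above the median level, and 5, 11 and 1 with the mean of all probe sets. It called 0, 0 and 0 with an estimated correlation, as did fry, and 18, 18 and 4 without the second arrays of both KDM5A groups, where each lone array is assumed to vary like the empty vector pair. Leaving out each array in turn, with the lone array of its group assumed to vary like the other groups, gave 0 to 14, 5 to 14 and 1 to 13 lists. The covariance of 0.0115 then lay between 0.00643 and 0.0268, at 0.0222 and 0.0268 without the first and second empty vector array, where 1 control array carries all of the shared error. The simulation of the covariance with the spread of the replicate block fit was not run.

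The direction of 4 lists depended on single arrays. Without the second arrays of both KDM5A groups, the KDM5A-H483A median against empty vector was 0.18 for the matrix, -0.14 for the mitochondrial ribosome and -0.23 for ribosome biogenesis. Leaving out 1 array at a time gave medians from -0.62 to 0.18, from -0.14 to 0.57 and from -0.23 to 0.62 for these lists, from -0.14 to 0.63 for interferon-stimulated genes with wild-type KDM5A against empty vector, and from -0.14 to 0.68 for ribosome biogenesis between the KDM5A forms. For the last list the median of 0.06 without the first wild-type KDM5A array lies above 0 while camera points down.

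Single genes that changed sign, none of them past the threshold, did so as follows. With the mean of all probe sets, the log2 fold change against empty vector was 0.0552 for Kdm5b and -0.00344 for Kdm5c with wild-type KDM5A, -0.0159 for Kdm5a and -0.0949 for Ccn1 with KDM5A-H483A, and -0.11 for Kdm5a between the KDM5A forms. With arrays centred on their median, Ppbp was at -0.00266 between the KDM5A forms. Leaving out 1 array at a time for wild-type KDM5A against empty vector gave -0.0305 to 0.0974 for Kdm5a, -0.31 to 0.18 for Kdm5b, -0.37 to 0.10 for Kdm5d, -0.0238 to 1.22 for Nr4a2, -0.14 to 2.33 for Usp18 and -0.50 to 2.29 for Xaf1. For KDM5A-H483A against empty vector it gave -0.0275 to 0.46 for Kdm5b, -0.18 to 0.0888 for Kdm5c, -0.0527 to 0.97 for Hspa8, -0.0743 to 1.3 for Mrps25, -0.26 to 1.17 for Mrpl12, -0.23 to 1.54 for Ncl and -0.0884 to 1.1 for Rrp12. Between the KDM5A forms it gave -0.00344 to 0.22 for Kdm5a, -0.12 to 0.12 for Ppbp, -0.25 to 0.16 for Chodl and -0.13 to 0.16 for Mycn. For the alternatives that keep all arrays the cause of a moved count or a changed sign was not tested. Low signal over background limits what can be seen, as for 4 of the 6 Kdm5a probe sets, whose mean levels lay at or below the 42.8th percentile of all probe sets.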

Other observations

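The tests on plate density, RNA degradation, cells of another type and shared control arrays were chosen after the result was seen. The genes below were picked for their size after the data were seen. Across both KDM5A groups, 165 genes lay at least 1 log2 unit apart between replicate arrays with the same sign, 147 higher in the first arrays and 18 higher in the second, and 0 genes lay as far apart with opposite signs. In empty vector, 133 of the 165 genes had the same sign. The genes higher in the first arrays included Mme, which encodes the peptidase neprilysin (14-fold for wild-type KDM5A and 15.1-fold for KDM5A-H483A), Penk, which encodes proenkephalin (15.7-fold and 7.73-fold), Hmcn1, the gene of the matrix protein hemicentin (13.0-fold and 10.8-fold), and Fos, an immediate early transcription factor (6.13-fold and 8.52-fold). The genes higher in the second arrays included Ankrd1 (3.33-fold and 4.59-fold), Ccn2, a matricellular growth factor gene (2.61-fold and 2.32-fold), and Serpinb2, a plasminogen activator inhibitor gene (3.27-fold and 2.23-fold).

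The second KDM5A-H483A array also stood low for Y-linked genes. Uty stood at 6.17 there and between 7.06 and 7.61 in the other 5 arrays, and Kdm5d at 5.70 against 6.15 to 6.62, while Eif2s3y, at 5.66 against 5.79 to 6.16, differed less. Xist lay between 5.51 and 5.70 in all 6 arrays.

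Of the explanations weighed for this split of the KDM5A arrays, RNA degradation in the second arrays would raise the signal at the 3' end of transcripts over that at the 5' end. The mean 3' minus 5' signal of the actin and Gapdh control probe sets was 1.33 and 1.51 log2 units in the first and second wild-type KDM5A arrays (difference 0.180). It was 1.61 and 1.5 with KDM5A-H483A (-0.107) and 1.75 and 1.58 with empty vector (-0.165), with both wild-type KDM5A arrays below both empty vector arrays. The 2 controls disagreed for wild-type KDM5A, with actin at 1.36 and 1.21 and Gapdh at 1.31 and 1.82 in the first and second arrays. The labelling kit named in the protocols leaves unclear how this signal reads, so RNA degradation stays open. Cells of another type in the second cultures would raise that type's markers while the matrix genes were lower by 0.78 and 0.83. The highest median among 5 marker lists, second minus first array, was 0.172, for neural markers with wild-type KDM5A (0.0102 with KDM5A-H483A). Among neural markers, Sox2 stood at 6.7 and 6.4 in the second arrays (5.7 and 5.8 in the first) and Stmn2 at 7.6 and 8.0 (6.9 and 7.0), while S100b and Syp were lower in both second arrays. The medians argue against a large share of epithelial, endothelial, leukocyte or muscle cells, and less clearly of neural cells. The brightest markers of these types in the second arrays were Krt19 at 6.30 and 7.01 (5.25 and 5.42 in the first arrays), Flt1 at 7.52 and 7.09 (6.97 and 7.11), Laptm5 at 6.44 and 6.57 (6.03 and 6.68), Nes at 8.15 and 8.56 (7.91 and 8.02) and Mef2c at 6.71 and 6.49 (7.22 and 7.54), and 2 neural markers exceed a level of 8 with empty vector. Another hypothesis that stays open is that the first KDM5A cultures were denser, which would lower targets of the density-sensitive factor YAP: the median of 22 such targets lay at the 69.8th percentile of 10000 random lists matched on level for wild-type KDM5A and at the 7.44th for KDM5A-H483A, with Ankrd1, Ccn2 and Crim1 lower and Ccdc80, Tgfb2 and Rbms3 higher in the first arrays of both groups, so the test decided nothing.

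For the gene lists, the 6 arrays can be paired in 15 ways, too few for a share under 0.05. The real grouping gave 14 list calls over the 3 comparisons by camera with the preset correlation, the fewest of the 15 pairings. The other pairings gave 17 to 56, so list calls in this number came with any grouping of these arrays. The pairing with 56 calls put the first KDM5A arrays together and the second KDM5A arrays together, and limma called 460 genes in 1 of its comparisons, against 0 in each comparison of the real grouping (5634 and 1454 over the 3 comparisons at an unadjusted p under 0.05, with 5888 in another pairing where limma called 0), which points to a structure of the samples other than the groups. This is the replicate split described above seen again, and not separate support for it.

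Npnt, Ppbp, Mycn and Chodl were 4 of the 10 genes named for their p in each comparison against empty vector. Whether the shared empty vector arrays account for the likeness over all genes stays open. With no effect and each group's own spread simulated, the covariance of 0.0115 lay within the simulated 0.0104 to 0.0147, but the r of 0.34 above the simulated 0.21 to 0.32 and the rho of 0.29 below 0.32 to 0.35. With the spread pooled over groups, the covariance, r and rho lay below the simulated 0.0241 to 0.0311, 0.46 to 0.53 and 0.44 to 0.47. The simulated errors were independent between genes, while the correlation estimated within the gene lists reached 0.82. These ranges therefore do not cover correlated genes, and lying outside them decides nothing. An effect common to both KDM5A forms was not tested apart from the shared arrays.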
